A study of Mus musculus with 6 samples.

How the data were processed

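Total RNA of the cerebellar vermis was taken from 6 mice with the RNeasy Fibrous Tissue kit and made into libraries with the NEBNext Ultra II RNA kit, per the labels' protocols. The labels name 2 strains, dCas and LINE-1a, with 3 replicates each, which set the groups. Whether the replicates came from separate litters or days is not stated, so p-values measure the spread between these mice.

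The deposited values are normalized counts, a signal equal to the reads per feature divided by 1 size factor per library. The authors deposited 3 tables: cellular genes (21927 rows, of which 224 are all 0 and 890 are repeat elements), 50 unique ERV loci from ERVMap, and repeat elements from RepEnrich (18538 rows, of which 14257 are all 0). The submitters' processing notes name STAR 2.5.3a, Bowtie2 2.2.9, bedtools 2.27.1, SAMtools 1.9 and DESeq2 and the builds mm10 and GRCm38, without roles. The counter, the annotation and the use of strand are not given in the sources used here.

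In the gene and repeat tables every value was a whole multiple of the library's smallest step, within 0.001 reads, for 100% of values, which gives back whole reads. The gene table held 23483158 to 33445789 reads per library and the table of repeats between 420424 and 603366. The repeat table had its own size factors, between 0.861 and 1.31 when the gene step is divided by the repeat step, so each table was tested on its own. The 890 repeat elements in the gene table have the same reads there as in the repeat table, scaled by the size factors of the genes, and 530 of them were tested with the genes. They were noticed after the tests, and leaving them out was run as an added alternative. The ERV loci held 1280 to 2890 reads per library, which leaves most loci with few counts, and no count test was run on them.

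The main test was limma-trend 3.58.1 in R 4.3.3 on log2(normalized count + 1), for features with a mean of at least 10, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that scale, which understates the change of low genes. The ERV loci were fitted with no trend and no filter beyond a mean above 0. The tests kept 15800 features of the gene table (15270 genes and 530 repeat elements), 989 repeat elements (377 of them simple repeats) and 50 loci. edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives. Gene and repeat lists were tested by camera with a preset correlation of 0.01, on lists with at least 5 tested genes or 3 tested elements, with an estimated correlation and fry as alternatives. The tests, the lists, the alternatives and the rule for naming genes were chosen before the data were examined.

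The rule named up to 10 higher and 10 lower genes with the largest change, a mean of at least 50, no overlap between the groups and an adjusted p under 0.05, or, where fewer than 5 passed, the 5 of smallest p. From each list it took up to 4 members past the threshold or, where none passed, up to 2 of smallest p. It took up to 3 elements of smallest p from each repeat list, none past the threshold, of which the text names a part. Calb1, Pcp2, Itpr1, Gfap, Aif1, Cdkn1a and H2afx were always given, and so were the 5 ERV loci of smallest p. Some other genes that the rule gives are not reported here. The planned names for young L1 (L1Md_T, L1Md_A and L1Md_Gf) matched 0 rows, because the table splits these families into numbered subfamilies. The planned list of L1 outside L1Md therefore held all 112 L1 and Lx families, and 7 further repeat lists were written after the element names were seen. The list of mitochondrially encoded genes had 0 members in the table, and sex-linked genes were used only to read the sex of the animals.

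On simulated reads for the 15800 features of the gene table, limma recovered 2.99% of those changed 1.5-fold, 34.3% of those changed 2-fold and 89.4% of those changed 4-fold, with 7 false calls among 15600 unchanged features. For 989 repeat elements it recovered 40.3%, 83.6% and 100%, with 4 false calls. Each feature was drawn on its own, with no shift shared by the features of a library, so these rates need not hold for families that vary together. The smallest simulated change, 1.5-fold, lies above that of young L1 subfamilies such as L1MdTf_I (1.34-fold). Positions, lengths and GC come from GENCODE on GRCm38, matched by symbol, for 96.1% of the features tested from the gene table. Replicates were compared before averaging, and the chi-square per degree of freedom between libraries of 1 group was 27.8 to 140, far beyond sampling noise. Alternatives changed the pseudocount, the filter, the scaling, the weights, the block, the libraries and the tool. Sex as a covariate had been planned for the case of both sexes within each group, which did not hold, and was run as an added alternative with the male libraries alone, with the trend in length and GC removed, and with a choroid plexus covariate, the median log2 deviation of the choroid plexus markers in each library.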

Results

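RNA was sequenced from the cerebellar vermis, the midline part of the cerebellum, of 8-week-old mice. The study compared 3 dCas mice, the controls, with 3 LINE-1a mice, in which, by the study's description, the retrotransposon LINE-1 (L1) is activated. L1 is a repeat that copies itself through an RNA intermediate. Each mouse gave 1 library, so n = 3 per group throughout, and values below are means of normalized counts ± SD. The reads per library recovered from the gene table ran from 23483158 in LINE-1a 2 to 33445789 in dCas 3. The reads recovered from the table of repeat elements ran from 420424 in LINE-1a 1 to 603366 in dCas 3. The table of endogenous retrovirus (ERV) loci held far fewer, from 1280 in LINE-1a 3 to 2890 in dCas 3.

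The Y-linked genes showed that the groups differed in sex. Ddx3y, Uty, Kdm5d and Eif2s3y lay between 533 and 1863 normalized counts in all 3 dCas libraries and in LINE-1a 3, and between 0 and 3.23 in LINE-1a 1 and LINE-1a 2. Tsix, an antisense partner of Xist, was 9275 in LINE-1a 1, 13147 in LINE-1a 2 and 18.9 in LINE-1a 3. Counting by strand is not given in the sources used here, so Tsix cannot be told from Xist. By these genes LINE-1a 1 and LINE-1a 2 are female and the other 4 libraries male, and group and sex are partly confounded.

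The first comparison asked whether L1 RNA was higher in the LINE-1a mice, as the labels say of these animals. Most L1 subfamilies had higher mean values in LINE-1a vermis, by amounts that no subfamily carried past the threshold. L1MdTf_I was 346 ± 41.1 in dCas and 468 ± 96.2 in LINE-1a vermis, a log2 fold change of 0.42 ± 0.17 (SE), and L1MdA_I went from 372 ± 43.8 to 500.5 ± 103 (log2 fold change 0.41). The most abundant young subfamily, L1MdTf_III, was lower instead, at 9741 ± 1382 in dCas and 7099 ± 1974 in LINE-1a libraries (log2 fold change -0.48). These are among the L1 subfamilies young enough to hold copies that can still move.

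Of 112 tested L1 and Lx families, 89 had a log2 fold change above 0 and 23 below, with a median of 0.38. In limma, 0 passed a Benjamini-Hochberg adjusted p of 0.05, the smallest adjusted p was 0.305, and 54 were higher and 1 lower at an unadjusted p under 0.05. On the recovered reads, edgeR and DESeq2 also called 0 L1 families. L1MdTf_II (0.45), L1MdA_II (0.41), L1MdGf_I (0.41) and L1MdGf_II (0.40) had log2 fold changes like those of L1MdTf_I. L1MdA_III was at -0.10, and above 0 when every library was given the same total (0.18) or scaled by the size factors of the genes (0.10). L1MdTf_I lay between 0.927 and 0.935 times L1MdA_I in every library, so these rows are not independent and their values are uncertain. The higher values were not seen in every animal: L1MdTf_I was 357 in LINE-1a 1, within the dCas range of 304 to 386, and 530 and 516 in LINE-1a 2 and LINE-1a 3. Without LINE-1a 1, 49 L1 families passed as higher and 6 as lower. The gene table lists L1 families with the same reads, scaled by the size factors of the genes. There L1MdTf_I was 331 ± 65.7 in dCas and 525 ± 186 in LINE-1a vermis (log2 fold change 0.62), L1MdTf_III was at -0.28, and 107 of 113 tested families were above 0, with a median of 0.57.

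**Figure D1:**
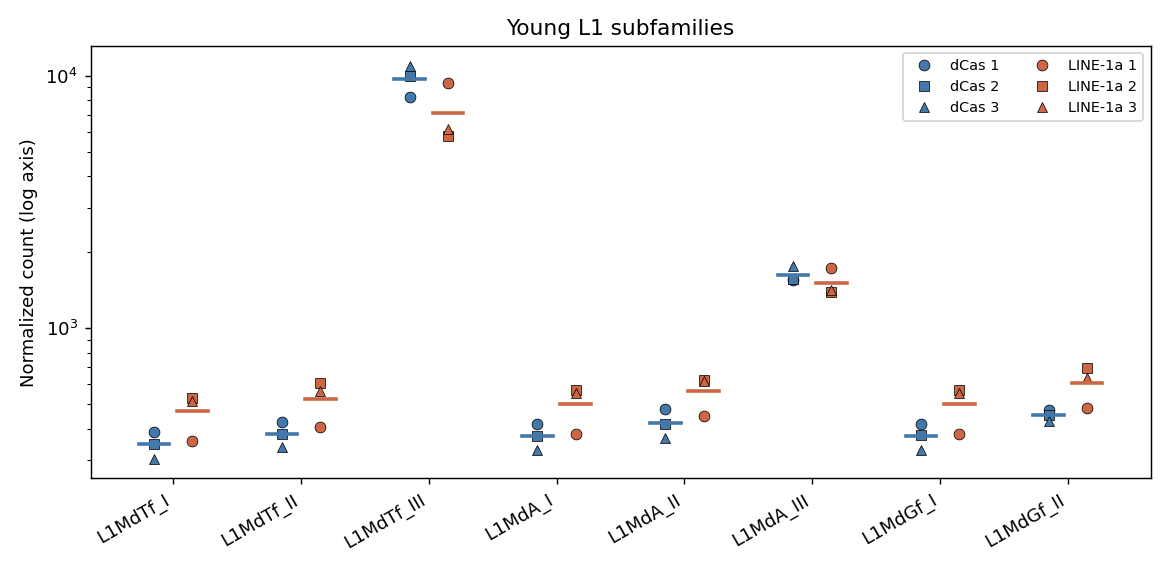
Normalized counts (log axis) of the 8 young L1 subfamilies in each library, with dCas in blue, LINE-1a in orange, 1 symbol per replicate number and a line at the mean of 3 libraries. L1MdTf_III, near 9741 in dCas libraries, lies far above the others and is lower in LINE-1a 2 and LINE-1a 3, where L1MdTf_I is higher.

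Among groups of repeats, the L1 and Lx families stood above the other repeats (camera with preset correlation, adjusted p = 2.17e-11), and the IAP elements, a class of mouse ERV, stood below them, with a median log2 fold change of -0.11 (adjusted p = 0.0327) that turned to 0.18 with equal totals and 0.09 with the size factors of the genes. These were 2 calls among 10 repeat lists, and both were lost with an estimated correlation (adjusted p = 0.63 for both). Ancient L1M families, grouped after the element names were seen, had a median of 0.47, with 50 of 54 above 0 (adjusted p = 2.09e-12 for the list, and adjusted p = 0.342 with an estimated correlation). Of its members, L1M2 was at 0.56 and L1ME3A at 0.71, neither past the threshold (adjusted p = 0.305 each). The Lx families had a median of 0.26, and the simple repeats, read from short tandem motifs, a median of -0.12, which turned to 0.15 with equal totals and 0.07 with the size factors of the genes. Both were called with the preset correlation, and both had an adjusted p of 0.342 with an estimated correlation. The young L1 subfamilies as a list did not pass (median 0.41, adjusted p = 0.0526), and passed as higher in 13 of 22 alternatives. B1 SINEs (median 0.12), B2 SINEs (0.15), MaLR elements (0.06), ETn and MusD elements (-0.02), MERVL and MT2 elements (0.08), other class II internal sequences (0.12), class I internal sequences (-0.03) and L2 and other LINE families (-0.14) did not pass. L2 and MIR families (0.07), DNA transposons (0.10) and the other L1Md subfamilies (-0.08) did not pass either.

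Over all 989 tested repeat elements, limma called 0, edgeR 1 lower and DESeq2 1 higher and 2 lower, with 93 higher and 54 lower at an unadjusted p under 0.05. MER5B, an old DNA transposon, had the smallest adjusted p (0.098), at 175 ± 9.18 in dCas and 101 ± 8.27 in LINE-1a vermis. The internal sequence RLTR4_MM-int, of the murine leukemia virus group, ranged from 7149 in LINE-1a 2 to 71480 in dCas 3. Without LINE-1a 1, 156 elements passed, 68 higher and 88 lower. The size factors of the genes moved the median log2 fold change of all repeats from 0.05 to 0.25.

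The ERV table listed values by locus, and asked which proviruses changed. Pmv6 and Pmv19 had identical values in every library, so not all loci were measured apart from each other. Of 50 loci, 40 had a log2 fold change below 0, limma called 0, and 7 were lower at an unadjusted p under 0.05. Xmv10, a xenotropic murine leukemia provirus, was 188 ± 37.1 in dCas and 47.5 ± 49.1 in LINE-1a vermis (log2 fold change -2.42, limma adjusted p = 0.229). Pmv16 (-1.28), Mpmv3 (-1.04), Xmv12 (-1.77) and Xmv16 (-1.12) were the next by p, and the highest dCas mean among them was 15.1, that of Xmv16. Emv2, singled out after its values were seen, ran from 180 in LINE-1a 3 to 1030 in LINE-1a 1. Without LINE-1a 1, 2 loci passed as lower.

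The comparison of cellular genes asked which genes differ in the vermis between LINE-1a and dCas mice. LINE-1a vermis held 21 genes that rose and 2 that fell. Il19, a cytokine of the interleukin-10 family, rose from 3.65 ± 0.892 to 685 ± 19.5 normalized counts, a log2 fold change of 7.23 ± 0.25 (SE) with an adjusted p of 2.05e-06 in limma. Cracr2a, a regulator of calcium channels, rose from 31.5 ± 5.37 to 452 ± 107. Pglyrp1, a protein that binds bacterial peptidoglycan, rose from 419 ± 70.3 to 2615 ± 637. Chil1, a chitinase-like protein that astrocytes make, fell from 765 ± 48 to 274 ± 64.3 (log2 fold change -1.50).

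Il19 lies on chromosome 1 (GRCm38, 130932656 to 130940115). Cracr2a is on chromosome 6 (127561338 to 127674248, log2 fold change 3.79) and Pglyrp1 on chromosome 7 (18871331 to 18890459, log2 fold change 2.62). C1qtnf1, a secreted protein, rose by 3.76 on the log2 scale, and Lgals3bp, a secreted binding partner of galectins, by 2.96. The 2 genes start 35.5 kb apart on chromosome 11. Msln, which codes for mesothelin, rose by 2.85, Slc25a24, a mitochondrial carrier, by 2.62, Fgf5, a growth factor, by 2.54, Rbm24, an RNA-binding protein, by 2.53, and 3425401B19Rik by 3.21. The adjusted p of these 7 genes in limma ran from 0.00171 to 0.0334. Further down the list, Lgals3, a galectin, rose from 95.2 ± 13.6 to 263 ± 47, a call lost in 10 of 22 alternatives, while that of Lgals3bp was lost in 7 and that of Chil1 in 6. Besides Chil1 only Gal3st2b passed as lower, with a mean of 30.6 in dCas and 2.12 in LINE-1a libraries, below the level set for naming and given because it was 1 of only 2. Hmcn1 (-1.34), Traf1 (-1.15), Plch1 (-0.84) and Agbl2 (-0.73) had the next smallest p among lower genes and did not pass.

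The gene table gave 15800 tested features, of which 530 are repeat elements that the authors listed there as well, and 0 of these passed. Without them the same 23 genes passed. Of the 15800 features, 3497 (22.1%) did not overlap between the groups. The mean share over all splits of the libraries is 10%. Features vary together, so the share in a single split can lie far from that mean, and the excess was not tested. At an unadjusted p under 0.05, 1255 were higher and 1162 lower. edgeR called 23 genes, 22 of them shared with limma, and DESeq2 139, of which 99 were higher. The number of calls was 40 without dCas 1, 14 without dCas 2, 15 without dCas 3 and 11 without LINE-1a 3. With sex as a covariate, chosen after the data were seen, 3 genes passed, Il19 and Cracr2a among them, and 0 passed in the male libraries alone, where the LINE-1a group is 1 library. Both female mice are in the LINE-1a group, so that covariate also leaves LINE-1a 3 alone to be compared with the dCas libraries. The changes themselves stayed about as large. Over the 23 called genes, the median log2 shift from the dCas mean, in the direction of the call, was 2.32 in LINE-1a 3. It was 2.52 in the female libraries. Il19 was at 7.18 with the covariate. The 23 genes were chosen with LINE-1a 3 in the fit, and 1 male library cannot separate group from sex.

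**Figure D2:**
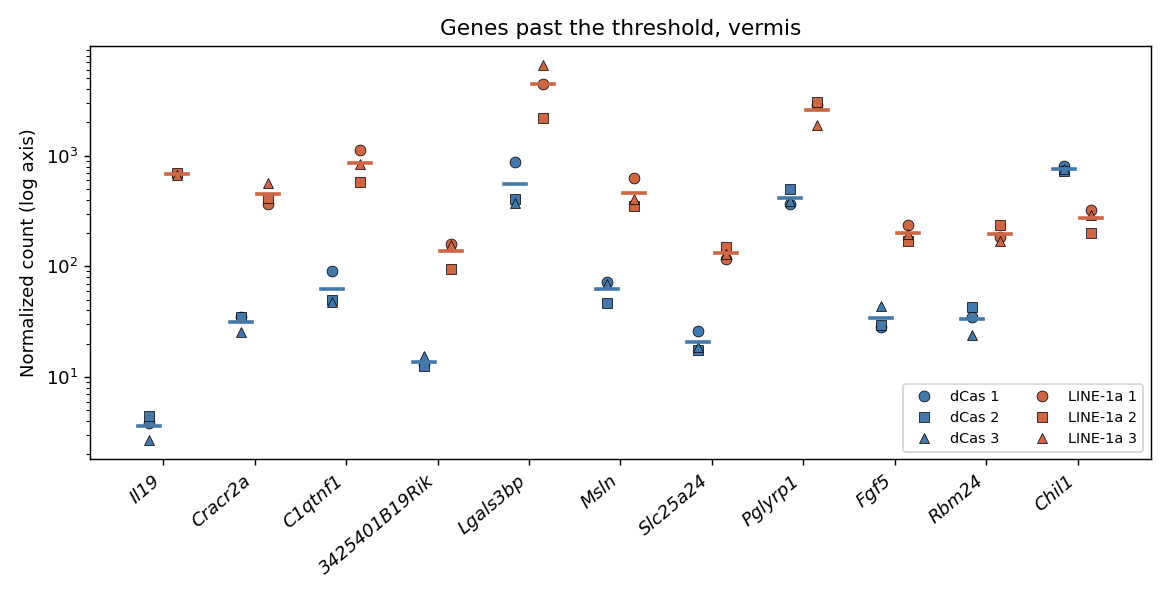
Normalized counts (log axis) of the 11 named genes past the threshold in each library, with dCas in blue, LINE-1a in orange, 1 symbol per replicate number and a line at the mean of 3 libraries. The groups do not overlap for any of these genes, and Il19 has the widest gap, from 3.65 to 685.

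Gene lists fixed before the data were examined were compared with all other genes by camera. Of 33 lists, 2 stood higher and 8 lower in LINE-1a vermis with the preset correlation. With an estimated correlation 0 were called (smallest adjusted p = 0.874). By fry, which tests a list against no change and not against the other genes, 0 were called (smallest adjusted p = 0.676). The interferon-stimulated genes, the antiviral program that type I interferon switches on, had a median log2 fold change of 0.63, with 29 of 34 members above 0 (camera adjusted p = 1.21e-08, and adjusted p = 0.874 with an estimated correlation). Lgals3bp passed over all genes, and adjusted over the list alone 14 members were higher and 1, Cmpk2, lower. Ifi27l2a was 37.9 ± 18.2 in dCas and 154 ± 53.3 in LINE-1a vermis, Ifit1 188 ± 91.9 and 481 ± 112, and Isg15 39.8 ± 8.56 and 82 ± 15.2. These 3 were picked after their values were seen. The list's median relative to the dCas mean was 0.72, 0.51 and 1.18 in the LINE-1a libraries and 0.25, -0.06 and -0.23 in the dCas libraries.

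The other list that stood higher was that of the immediate early genes, which neurons switch on with activity, with a median of 0.37 and 17 of 22 members above 0 (camera adjusted p = 0.0414, and adjusted p = 0.874 with an estimated correlation). Nr4a3 had a log2 fold change of 0.71 and Ier5 of 0.89. LINE-1a 3 did not share this, at -0.05, and the list's median was -0.05 with sex as a covariate.

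The camera adjusted p of the 8 lists that stood lower ran from 1.5e-14 for the clustered protocadherins to 0.0406 for the endothelial markers, and each had an adjusted p of 0.874 with an estimated correlation. Sterol synthesis genes, which make cholesterol, had a median of -0.45, with 20 of 22 members below 0 and 3, Dhcr7 (-0.82), Sc5d (-0.66) and Ebp (-0.47), past the threshold adjusted over the list alone. Astrocyte and Bergmann glia markers had a median of -0.36, with Gja1, the main astrocyte gap junction protein, at -0.90 and S100b at -0.46. Oligodendrocyte and myelin markers had a median of -0.35, with Mag at -1.03 and Car2 at -0.56. Heat shock chaperone genes had a median of -0.30, with Cryab at -0.69, past the threshold over the list alone, and Hspa4l at -0.53. Brainstem and cerebellar nuclei markers (-0.49), endothelial and mural markers (-0.28) and ER stress genes (-0.13) were called as well, with Slc6a5 at -0.54, Th at -1.94, Slc2a1 at -1.03, Ly6c1 at -0.53 and Hsp90b1 at -0.71, although Edem1, of the ER stress list, was at 0.76.

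Clustered protocadherin genes, cell-surface proteins that neurons use to tell self from other, had the lowest median, at -0.56, with 55 of 56 members below 0. Pcdhb22 was at -0.80 and Pcdhb9 at -1.10. Many of these genes overlap or share exons, so their values are uncertain and not independent. These lower medians were mostly set by LINE-1a 2 and LINE-1a 3. For the protocadherins the median was -0.21 in LINE-1a 1, -1.08 in LINE-1a 2 and -0.40 in LINE-1a 3, and for the astrocyte markers 0.01, -0.54 and -0.33. LINE-1a 2 also lay farthest from the other libraries on the first principal component, which held 53.4% of the variance, and it had the fewest gene reads and the highest rRNA share of the repeat table, 10.2% against 5.39% to 7.86% in the other libraries.

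Markers of Purkinje cells, the output neurons of the cerebellar cortex, were not called, with a median of 0.02. Calb1 was 5801 ± 657 in dCas and 5873 ± 1109 in LINE-1a vermis, and Pcp2 19010 ± 2087 and 15152 ± 4147. Itpr1, the calcium release channel of Purkinje cells, had a log2 fold change of -0.61 and Rgs8 of -0.98, while Prkg1 was at 0.70, none of them past the threshold. The calcium signalling genes of Purkinje cells had a median of 0.00, with Cacna1a at 0.77 and Cacna2d2 at 0.47, and the ataxia disease genes a median of 0.08, with Aptx at -0.46. Granule cell (0.06), inhibitory interneuron (0.01), unipolar brush cell (-0.21) and oligodendrocyte precursor (-0.19) markers were not called. Of their members, Grin2c was at 0.72, Cbln3 at -0.81, Cdh22 at 0.68, Slc17a6 at -0.83, Plcb1 at 0.33, Neu4 at -0.81 and Fyn at 0.42. Nor were postsynaptic (0.17), synaptic vesicle (-0.06), DNA repair (-0.01) or p53 target genes (0.08), with Cdkn1a at -0.14 and H2afx at 0.59. In these lists Gria3 was at -0.43, Vamp1 at -0.64, Napb at -0.64, Nbn at 0.65, Pmaip1 at -1.50 and Trp53inp1 at 0.55. Factors that restrict or silence retroelements had a median of 0.09, with Fam208a at 0.41 and Dnmt1 at -0.84. For the Purkinje, calcium signalling, interneuron, p53 target and ribosomal protein lists the median lay above 0 while camera, which compares a list with the other genes, put them lower.

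Microglia markers had a median of 0.06. Laptm5, a lysosomal protein, was higher adjusted over the list alone, at 605 ± 189 and 1711 ± 394, Aif1 was 88.5 ± 30.8 and 121 ± 12.4, and C1qa had a log2 fold change of 0.33. The genes of phagocytic microglia had a median of -0.09, with Lgals3 as the only member past the threshold. Reactive astrocyte genes had a median of 0.02 and Gfap a log2 fold change of -0.86, not past the threshold. Lcn2, at 120 ± 90.9 in dCas and 17.3 ± 3.16 in LINE-1a vermis (log2 fold change -2.33), and Psmb8, at 55.2 ± 27.2 and 135 ± 36.6 (1.36), went in opposite directions, without overlap between the groups, and did not pass either. Apoptosis and inflammasome (0.10), meningeal (0.11), red blood cell (-0.20), ribosomal protein (0.02), oxidative phosphorylation (-0.07), histone (0.11) and Zfp (-0.03) genes were not called, although Zfp710 was higher over its list alone (log2 fold change 1.70). In these lists the log2 fold changes were 0.45 for Pycard, 1.19 for Foxc1, -0.57 for Col1a2, -0.61 for Slc4a1, -0.34 for Hbb-bt, -0.45 for Rpl15, 0.55 for Rpl10a, -0.72 for Cox6b2, 0.59 for Atp5g2, 0.46 for Hist1h2be, -0.27 for Hist2h2be and 0.72 for Zfp771. Choroid plexus markers had a median of 1.13, with 11 of 14 members above 0, and were not called (camera adjusted p = 0.334). They varied widely between libraries of both groups. Their medians relative to the dCas mean were 2.82, -1.23 and -1.52 in dCas 1 to 3 and -0.79, 1.42 and 2.88 in LINE-1a 1 to 3. Over the 6 libraries these ranked with the medians of the L1 and Lx families (Spearman rho 0.829) and of the interferon-stimulated genes (rho 0.771). Of the choroid plexus markers, Clic6 was at -0.50 and Ttr, the most abundant of them, at 2.96 ± 2.18 (SE). Ttr was 81570 in dCas 1 and 102965 in LINE-1a 3, and 144 in dCas 3.

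**Figure D3:**
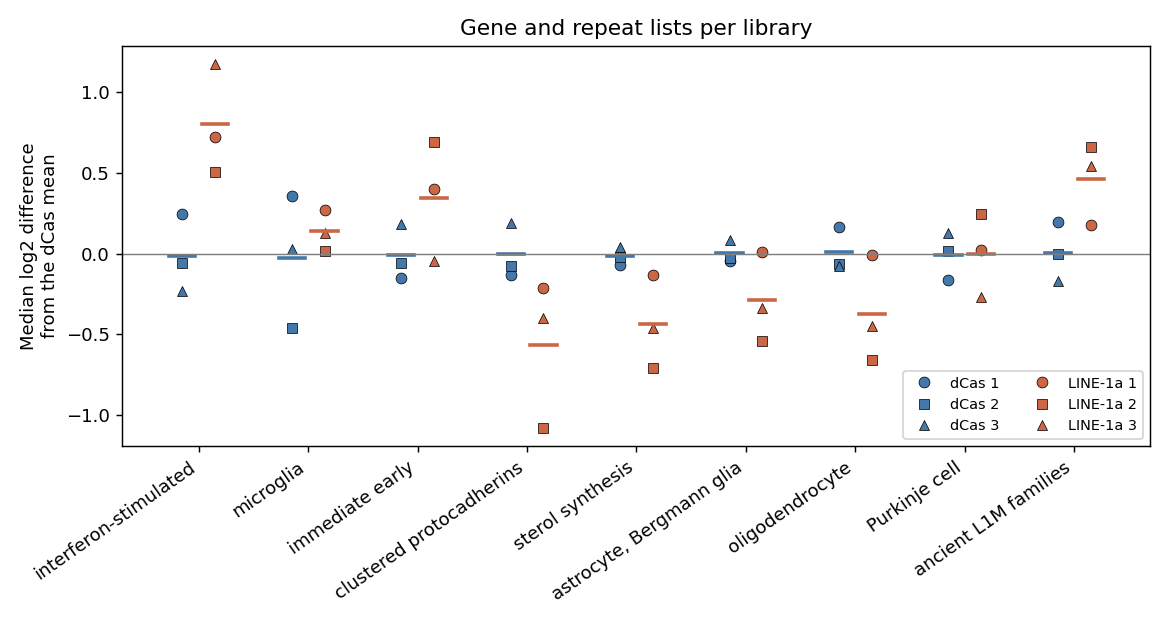
Median log2 difference from the dCas mean of 8 gene lists and the ancient L1M families in each library, with dCas in blue, LINE-1a in orange, 1 symbol per replicate number and a line at the mean of 3 libraries. The interferon-stimulated genes are above all dCas libraries in each LINE-1a library, the lowest at 0.51, while the glial and protocadherin lists are lowest in LINE-1a 2.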

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

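The alternatives with sex as a covariate, with male libraries only, with the length and GC trend removed, without the repeat elements of the gene table and with a choroid plexus covariate, and the added repeat lists, were chosen after the data were seen. The count of genes, 23, was 36 with equal totals, 139 with DESeq2, 3 with sex as a covariate, 0 in male libraries only, 36 with the length and GC trend removed, 23 without the repeat elements and 20 with the choroid plexus covariate. Both sex alternatives compare LINE-1a 3 alone with the male dCas libraries. Over the 23 genes the median log2 shift was 2.32 in LINE-1a 3 and 2.52 in the female libraries. These genes were called with LINE-1a 3 in the fit, so their shift in that library was favoured by the choice. It says nothing about sex. Leaving out 1 library gave 11 to 40 genes. Array weights gave 9043 genes, 253 repeat elements, 66 higher L1 families and 5 repeat lists. For the genes the estimate of the weights stopped before it converged and gave dCas 2 and LINE-1a 3 weights of 9.24 and 6.15, against at most 0.527 for the other 4 libraries. The cause of a moved count was not tested.

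The count of repeat elements, 0, was 1 with equal totals, 1 with edgeR and 3 with DESeq2, and 0 to 156 when 1 library was left out, the highest without LINE-1a 1. The count of higher L1 families was 0 to 49 in the same way. The count of ERV loci, 0, was 1 with equal totals and 2 in male libraries only, and 0 to 2 when 1 library was left out. The 10 gene lists became 0 with an estimated correlation and 0 with fry. The 2 repeat lists became 5 with no filter, 1 with equal totals, 1 with edgeR, 1 with the gene size factors, 0 with an estimated correlation, 0 with fry, 5 with sex as a covariate, 5 in male libraries only and 1 with the choroid plexus covariate, and 1 to 5 when 1 library was left out.

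Calb1, with a log2 fold change of 0.01, was -0.24 with array weights, -0.0059 with DESeq2, -0.30 with sex as a covariate and -0.30 in male libraries only, and -0.12 to 0.16 when 1 library was left out. L1MdA_III was 0.18 with equal totals and 0.10 with the gene size factors. The immediate early list was -0.048 with sex as a covariate, -0.048 in male libraries only and -0.040 with array weights, and the ER stress list 0.065 with array weights. The median of the IAP elements was 0.18 with equal totals and 0.090 with the gene size factors, and that of the simple repeats 0.15 and 0.075. The cause was not tested. Calls were lost, with the direction kept, in 11 of 23 alternatives for the immediate early genes, 9 for the endothelial list and 6 for the ER stress list, and in 8 of 22 for the IAP elements, 10 for Lgals3, 7 for Lgals3bp and 6 for Chil1. The immediate early, ER stress and IAP lists also lost their calls in the alternatives that turned their medians. The immediate early call was thus kept in 9 of 23 and the IAP call in 12 of 22. The young L1 list passed in 13 of 22.

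With the replicate number as a block, 24 genes passed, 18 of them shared, with 0 repeat elements, 0 ERV loci, 0 L1 families, 10 gene lists and 2 repeat lists. Same-numbered libraries correlated at -0.26, 0.16 and -0.10, which gave no sign that the numbers pair the mice. With 3 libraries per group a pairing of small effect cannot be excluded. edgeR and DESeq2 were not run on the ERV loci, and DESeq2 was not run on the lists. The main ERV fit already has no filter. The ERV table holds 2890 reads at most.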

Other observations

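The tests of sex, of the young against the ancient L1 subfamilies, of the scaling of the repeats, of microglia and of choroid plexus were chosen or given their final bounds after the results they concern were seen. The removal of the length and GC trend was chosen after the data were seen and before its result was. Its further condition, a confidence interval between the libraries above 0, was not part of that first wording. The splits of the libraries, the linked-DNA test and the test of long genes were set before their results were seen. To exclude linked DNA, a margin beyond the SD of the random sets (4.36) was also required, which was not set in advance.

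Several genes near the top of the list are neighbours. Ifi203, Ifi213 and Mndal, interferon-inducible genes of 1 cluster on chromosome 1, were among the 100 genes of smallest p, with log2 fold changes of 1.27, 2.18 and 1.17. Slc14a2 and Slc14a1, which code for urea transporters, start 46.1 kb apart on chromosome 18, at 2.42 and 1.69. Ide, the insulin-degrading enzyme, and Btaf1 on chromosome 19 were at 1.08 and 1.06. Relative to its mean, Il19 varied least of the 10 named higher genes, between 665 and 704 in the 3 LINE-1a libraries.

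The summed signal of the 8 young L1 subfamilies was 13708 ± 1233 in dCas and 11773 ± 1547 in LINE-1a libraries (SD, n = 3). L1MdTf_III made up 66.6% to 74% of it in dCas libraries, 69.1% in LINE-1a 1, 53.7% in LINE-1a 2 and 55.9% in LINE-1a 3. Without L1MdTf_III the sum was 3967 ± 150 and 4675 ± 429. With the size factors of the genes the sum was 12957 ± 499 and 12766 ± 1164, and without L1MdTf_III 3774 ± 448 and 5190 ± 1355, so the lower sum depends on the scaling. These sums were formed after the values were seen, and none was tested.

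With 3 mice per group there are 10 splits of the 6 libraries, so the share of splits with as large a result cannot fall under 0.05. The real split called 23 genes and the highest other split 10, and 1 of the 10 splits gave as many. For repeat elements and ERV loci the real count and the highest other count were 0, so 10 of 10 splits gave as many. For gene lists the real count was 10 and the highest other 16, with 6 splits as large, and for repeat lists 2 and 5, also with 6. The other splits are still uneven in the groups, so they keep part of any difference between them.

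The 23 called genes may partly reflect the sex of the animals, because both female mice are in the LINE-1a group. All 23 lay outside the dCas range in the male library LINE-1a 3, but they were chosen with that library in the fit, so this says nothing. Of 11 genes called without LINE-1a 3, 7 lay outside the dCas range there in the direction of the call, against 54.6% of all features tested from the gene table. These shares do not compare like with like, because 5 of the 11 lie on the sex chromosomes. The 4 that did not are Y-linked. Tsix did, at 18.9 in LINE-1a 3, far under its values in the females. The 6 autosomal genes, led by Il19 and Cracr2a, all did. Their log2 differences from the dCas mean were 2.18 (Pglyrp1) to 7.18 (Il19) in LINE-1a 3. In the female libraries these were 2.84 to 7.25. So for these 6 genes the difference was also seen between male mice, but 1 male library cannot settle the question. Linked DNA from another strain or around a transgene could also place called genes together, but 14 pairs of the 100 genes of smallest p started within 2 Mb, against a median of 14 and a 95th percentile of 22 in 10000 random sets. That count met the bound set in advance only as a tie. A short stretch of few genes stays open, and so does a longer segment with changed genes farther apart than 2 Mb. Chromosome 1 held 13 of the 100 genes, where 5.97 were expected, and chromosome 14 held 9 (3.48). Chromosomes 10 and X held 0 (4.79 and 3.45). Of the called genes, Il19, Chil1, Gal3st2b, Hdac4 and Ptprn lie on chromosome 1. These counts were not tested.

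The higher L1 values could be an activation limited to the young subfamilies, but their median minus that of the ancient L1M families was -0.061 (SE 0.040), with a 95% confidence interval of -0.17 to 0.05, far under the young median of 0.41 that this needs. The difference is between medians over subfamilies, and its SE comes from the spread of the libraries' medians. Scaling of the repeat table cannot produce the L1 median minus that of the other repeats, which no size factor changes. This contrast was higher by 0.36 (SE 0.17), nearly the whole of the L1 difference of 0.37 (SE 0.15). The young median minus that of all repeats stayed at 0.31 to 0.36 across the scalings tried. These values argue against the size factors as the source of the observed difference. The contrast had a 95% confidence interval of -0.12 to 0.83, so whether it exceeds the spread between mice stays open. Choroid plexus RNA stays open, since with the libraries' choroid plexus score as a covariate the difference in the L1 median went from 0.37 (SE 0.15) to 0.29 (SE 0.11), with a 95% confidence interval of -0.05 to 0.62. More RNA from long genes, whose introns hold old L1 copies, stays open too. Its test was the rank correlation across genes of each gene's deviation with its genomic length. This was 0.10 in LINE-1a 2, 0.27 in LINE-1a 3 and 0.16 in dCas 1. The bound set in advance needed LINE-1a 2 and LINE-1a 3 above every other library. The median of the longest genes, relative to the dCas mean, was 0.17, -0.003 and -0.16 in dCas 1 to 3. It was 0.03, 0.36 and 0.26 in LINE-1a 1 to 3. These medians ranked the 6 libraries in the same order as the L1 and Lx medians, as this explanation would give. Genes are not independent replicates, and a wider activation of L1 of all ages was not separated from the explanations left open.

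Why the interferon-stimulated genes stood higher was not settled, and a link to L1 activation was not tested. A trend with gene length and GC is argued against by the libraries' medians. After its removal they differed by 0.89 (95% confidence interval 0.17 to 1.60), against 0.81 (0.14 to 1.49) before. The list's median was then 0.66. Camera with the preset correlation called the list again (adjusted p = 3.15e-10). That adds little, because before the removal it gave smaller adjusted p-values in some splits that mixed the groups than in the real one. Choroid plexus RNA as the whole cause is argued against narrowly, since with its score as a covariate the difference between the groups went from 0.81 (SE 0.24) to 0.70 (SE 0.20), with a 95% confidence interval of 0.05 to 1.35. Sex stays open, with the list at 1.18 in the only male LINE-1a library, above the highest dCas library at 0.25. Microglia stay open too. Their markers had a median of 0.058, with a 95% confidence interval of -0.63 to 0.75. The interval is centred on the median over genes, and its width comes from the spread of the libraries' list medians. By camera the list also gave smaller adjusted p-values (4.51e-17 and 2.0e-12) in splits that mixed the groups than in the real one (1.21e-08). Each such split is still uneven in the groups, so it keeps part of any difference between them. The list did not pass with an estimated correlation (adjusted p = 0.874), so the call itself is not secure.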
